A study of Homo sapiens with 12 samples.

How the data were processed

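Total RNA of SK-MEL-5 and MALME-3M cells, untreated or treated with IFN-γ for 24 h, was sequenced in 12 libraries, 3 per group. Per the labels' protocols the cells were seeded in triplicate wells. The labels give no replicate numbers, so replicates were numbered within a group only to name them, and no libraries were paired. Line, IFN-γ dose (150 ng/mL for SK-MEL-5, 200 ng/mL for MALME-3M) and culture medium differ together, and no comparison between the lines can part them.

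The authors deposited, for each library, a table of read counts per gene and a table of transcript abundances. The gene counts are whole numbers per gene symbol and were deposited without normalization, per the file headers and their summary lines, which are those of HTSeq. The abundance tables hold an estimated count and a TPM value (transcripts per 1e6 transcripts) for each transcript, per the file headers, which are those of kallisto. The submitters' processing notes name cutadapt, STAR, SAMtools, kallisto and HTSeq, without versions, and the build hg38. The gene annotation, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. The tables do not tell PCR duplicates apart, so intervals and floors cover counting error only.

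The gene tables had 44700 genes, 15830 of them assembled loci without a symbol, and 34075 had a count in at least 1 library. The 5 summary lines were kept out of library sizes and tests. Alignments reported as not unique were 7.47 to 13.7 times the gene counts, those with no feature 0.533 to 0.850 times, and ambiguous ones 4.19% to 4.54% of the gene counts. Gene counts totalled 15514412 to 22921184 per library. At this depth 3 counts over the 3 libraries of a group, the floor used here, correspond to 0.0498 to 0.0572 CPM. A fold against a group with 0 counts was computed against that floor and is a lower bound. With 1 to 3 counts, the ratio of counts is given with its 95% Clopper-Pearson interval. Replicate libraries differed by more than sampling noise, with a chi-square of 6.35 to 19.3 per gene between pairs of one group, so no pair was counted as 1 sample.

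The transcript tables had 361686 transcripts, of which 200989 were assembled and 160246 could be tied to 20262 genes by GENCODE 29 on GRCh38. One assembled transcript of 336 nt took 46.6% to 57.7% of TPM in each library, so TPM was used for description only. The estimated counts of annotated transcripts were summed to genes, rounded to whole numbers and used as an alternative, in which 12502 genes were tested. Transcripts tied to genes held 49.9% to 55.2% of the estimated counts of a library, and assembled ones 44.8% to 50.1%. The sums thus hold part of the reads, so a call lost there need not speak against the gene counts. Gene positions were taken from GENCODE 29 by symbol.

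Gene counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15810, and libraries were scaled by TMM. A negative binomial quasi-likelihood model with 1 mean per group was fitted to all 12 libraries together (8 residual degrees of freedom, common biological coefficient of variation 0.0955). The contrasts were treated against untreated in each line, the difference of these changes (MALME-3M minus SK-MEL-5) and untreated MALME-3M against untreated SK-MEL-5. Calls were made below a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. Where a group has few counts, these standard errors understate the error of the fold. This holds for BST2, IFI27, OAS2, IRF8 and GBP4 in SK-MEL-5 and for HLA-DRA, HLA-DQB1, IFITM1 and IFI44L in MALME-3M, among others. Means and SD of CPM used the TMM-scaled library sizes. Treated MALME-3M against treated SK-MEL-5 was added after the data had been seen.

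Of 34 gene lists, 30 had at least 5 tested members and were tested with camera from limma 3.58.1 with a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Of the lists' symbols, 3 matched no gene. The lists cover interferon signalling, antigen presentation, antiviral genes, GTPases, chemokines, checkpoint ligands, cell death, metabolism, stress, cell cycle, melanocyte states, pathway outputs and markers of other cell types. Counts of called members are given over all genes tested and adjusted over the list alone. List medians are given also with genes of 3 or fewer counts in a group set to their bound.

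Groups, contrasts, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except that the robust fit and leaving out assembled loci were added after the data had been seen. The rule named, for each response to IFN-γ, the 8 largest rises and 8 largest falls among called genes with a symbol, non-overlapping groups and a mean log2 CPM of at least 2. For the difference it named the 8 largest in each direction among genes also called in a line with a mean log2 CPM of at least 2, and between the untreated lines those with a mean log2 CPM of at least 3. It also named up to 4 called members of each list described with a mean log2 CPM of at least 0, and 23 genes of interferon signalling, its targets and the melanocyte lineage in every comparison. Some genes the rule chose are not reported here, and no others took their place. Markers of other cell types outside this rule, and the genes named in the closing observations, were chosen after their values were seen.

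The model was tested on simulated counts drawn from the real means and library sizes and the fitted trend of dispersion over expression. For each contrast separately, 200 genes were changed and the contrast was otherwise without effect. Changed genes had a mean of at least 1 CPM in the group that was changed. A trend smooths over genes of unusual spread, such as those far higher in 1 library, so the rates below do not cover them. Of 100 genes changed by 1 on the log2 scale the model recovered 90% for SK-MEL-5 (15410 genes tested) and 88% for MALME-3M (15404). It recovered 68% for the difference (15391) and 84% for the untreated lines (15391). Of 100 changed by 2 it recovered 100%, 100%, 94% and 100%. False calls were 11 of 201, 8 of 196, 10 of 172 and 7 of 191.

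The alternatives tried were DESeq2 size factors and upper-quartile factors in place of TMM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the transcript estimated counts, a log2 fold change of at least 1 in addition, a robust fit, each comparison's libraries fitted alone, mitochondrial and the 10 highest genes left out, assembled loci left out, and each library left out in turn. Tables and figures were made with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). With 3 libraries per group no single library was tested as an outlier.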

Results

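RNA was sequenced from a pair of human melanoma cell lines, SK-MEL-5 and MALME-3M, both established from metastases, with and without interferon gamma (IFN-γ), the cytokine that activated T cells and NK cells release and that signals through JAK kinases. The labels describe treatment for 24 h, at 150 ng/mL in SK-MEL-5 and at 200 ng/mL in MALME-3M. The 12 libraries fell into 4 groups of 3: untreated and treated SK-MEL-5, and untreated and treated MALME-3M. Counts assigned to genes totalled 15514412 to 22921184 per library. The group medians were 19789795 for untreated SK-MEL-5, 18881684 for treated SK-MEL-5, 16516813 for untreated MALME-3M and 21310368 for treated MALME-3M. Between 21389 and 23365 genes had a count above 0 in a library. Values below are gene counts per 1e6 counts (CPM, mean ± SD, n = 3) and log2 fold changes ± SE, and a called gene is one below an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15810 genes. The labels describe triplicate wells and do not say that replicates came from separate experiments. The p-values therefore measure the spread between these libraries, which may be technical.

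Libraries separated first by line and then by treatment. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.988 to 0.991 within a group, 0.977 to 0.982 between treatments of one line, and 0.803 to 0.818 between lines. The first principal component held 86.2% of the variance and parted the lines, and the second held 5.26% and parted treated from untreated libraries in both lines. The share of counts from MALAT1, a nuclear RNA, was 1.23% to 1.27% in untreated and 1.36% to 1.40% in treated SK-MEL-5, and 1.75% to 1.85% in untreated and 1.85% to 2.27% in treated MALME-3M.

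In SK-MEL-5, IFN-γ raised most listed genes of interferon signalling, antigen presentation and antiviral defence, though not all to high levels. IRF1, a transcription factor induced by interferons, rose from 5.05 ± 0.77 to 204 ± 2.1 CPM (log2 fold change 5.35 ± 0.11, edgeR adjusted p = 1.4e-17). WARS, the tryptophanyl-tRNA synthetase, rose from 538 ± 16 to 6320 ± 107 CPM. IDO1, the enzyme that opens the tryptophan ring (chromosome 8, 39902275 to 39928444, GENCODE 29 on GRCh38), had 2 counts in the 3 untreated libraries and 172 ± 11 CPM after treatment, a ratio of 4937.5 (95% Clopper-Pearson interval 1366.5 to 40777, counting error only). In all, 946 genes rose and 1114 fell, 13.03% of those tested, and 314 of the rises and 44 of the falls were at least 2-fold. CPM did not overlap between the groups for 29.1% of all tested genes, where chance gives 10%.

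Both presentation pathways rose in SK-MEL-5. Of 22 genes of MHC class I presentation, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.68 (camera adjusted p = 2.39e-39). TAP1, a subunit of the peptide transporter, rose from 20.5 ± 2.0 to 389 ± 13 CPM. B2M, the light chain of class I molecules, rose from 244 ± 10 to 920 ± 31 CPM, and PSMB9, a subunit of the immunoproteasome, from 5.58 ± 1.0 to 66.2 ± 5.6 CPM. Of 16 class II genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 3.10 (camera adjusted p = 1.85e-23). CIITA, the master activator of class II genes (chromosome 16, 10866222 to 10943021), rose from 2.59 ± 0.40 to 51.6 ± 5.8 CPM, and HLA-DRA, a class II heavy chain (chromosome 6, 32439842 to 32445046), from 2.73 ± 0.60 to 28.9 ± 3.8 CPM. HLA genes are polymorphic and share sequence, so their levels are uncertain where a line's alleles differ from the reference.

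Antiviral interferon-stimulated genes rose almost as a whole in SK-MEL-5, with 42 of 43 called higher and 0 lower (43 and 0 adjusted over the list alone; median 2.69, camera adjusted p = 8.56e-81). BST2, which tethers budding virions, rose by 6.89 ± 0.12 on the log2 scale and OAS2, a sensor enzyme of double-stranded RNA, by 6.16 ± 0.15. Both rose from few counts, so these SE understate the error. IFI44L had 0 counts before and 12.4 ± 0.74 CPM after treatment, at least 239.6-fold higher. Of 25 IFN-γ signalling components, 18 rose and 2 fell (18 and 3 adjusted over the list alone; median 1.40, camera adjusted p = 1.36e-21). Among them IRF8 rose by 7.76 ± 0.32, from few counts before treatment. Of 10 interferon-inducible GTPases, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 3.04, or 2.07 with genes of 3 or fewer counts in a group set to their bound (camera adjusted p = 4.94e-08). GBP4 rose by 7.86 ± 0.25, also from few counts, and GBP1 by 5.80 ± 0.15. In the list of apolipoproteins L and complement, 10 of 14 rose and 0 fell (11 and 0 adjusted over the list alone; median 2.58, camera adjusted p = 3.13e-22), with APOL1, a trypanolytic factor, up by 5.42 ± 0.081 and C1R, a protease of the classical pathway, by 2.75 ± 0.13.

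Another 6 lists were called higher in SK-MEL-5, with 4 to 11 members each called higher. Chemokines and cytokines had 10 of 21 higher and 1 lower (13 and 2 adjusted over the list alone; camera adjusted p = 1.19e-08). CXCL10 is a ligand of CXCR3, a chemokine receptor of T cells. It had 0 counts before treatment and 1.20 ± 0.034 CPM after it, at least 23.1-fold higher. Immune checkpoint and inhibitory ligands had 8 of 16 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 4.94e-08), among them CD274, which encodes PD-L1 (chromosome 9, 5450503 to 5470566), from 0.712 ± 0.18 to 8.35 ± 0.80 CPM. Cell death genes had 11 of 28 higher and 0 lower (13 and 2 adjusted over the list alone; camera adjusted p = 2.47e-07). They included CASP1, the inflammasome protease, at 2.41 ± 0.12 and MLKL, the effector of necroptosis, at 1.69 ± 0.11. NF-κB targets had 6 of 19 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 2.72e-04), with the adhesion receptor ICAM1 up by 2.73 ± 0.051. Tryptophan and kynurenine genes had 4 of 14 higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 7.34e-04). The unfolded protein response and amino acid stress list had 6 of 18 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 9.99e-04), with ASNS, asparagine synthetase, up by 0.43 ± 0.071. With an estimated correlation these 12 lists stayed called, with adjusted p of 5.06e-05 to 0.0348.

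Falls in SK-MEL-5 were smaller than rises. ADAM19, a membrane protease, changed by -1.19 ± 0.16 and SOCS2, an inhibitor of cytokine signalling, by -1.16 ± 0.12. Outside the 8 largest falls, the retinoid receptor RXRG changed from 44.8 ± 1.9 to 29.6 ± 1.2 CPM and S100B, a calcium-binding protein of the melanocyte lineage, from 167 ± 8.5 to 132 ± 6.9 CPM. MYC targets had 7 of 23 lower and 1 higher (7 and 1 adjusted over the list alone), with POLR1B, a subunit of RNA polymerase I, at -0.37 ± 0.054 (camera adjusted p = 0.00273, and adjusted p = 0.115 with an estimated correlation). Melanocyte differentiation genes had 9 of 26 lower and 0 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.207 with an estimated correlation). Without SK-MEL-5 untreated replicate 1 or treated replicate 2, the camera adjusted p of that list was 0.0740 or 0.0603. Oxidative phosphorylation had 5 of 31 lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.458 with an estimated correlation), and without untreated replicate 1 or 2 its camera adjusted p was 0.0789 or 0.0675. G2 and M phase genes had 3 of 28 lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.0382, and adjusted p = 0.458 with an estimated correlation). That list was not called without untreated replicate 1 or 2 or treated replicate 3 of SK-MEL-5, or without treated replicate 1 or 3 of MALME-3M, which share the fit (camera adjusted p 0.0735 to 0.123).

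The other 14 lists were not called in SK-MEL-5 by camera. They had, higher and lower, 5 and 3 of 31 constitutive proteasome genes, 3 and 5 of 15 iron and ferroptosis genes, 3 and 5 of 30 dedifferentiation and invasion genes, 1 and 1 of 11 neural crest genes and 0 and 2 of 25 S phase genes. The p53 targets had 2 and 3 of 21, MAPK output 1 and 4 of 20, shared melanoma antigens 0 and 1 of 17, glycolysis 3 and 1 of 21, and cholesterol synthesis 0 and 4 of 20 (camera adjusted p = 0.0868, and 0.0412 without SK-MEL-5 untreated replicate 3). Histones had 1 and 3 of 20, mitochondrially encoded genes 0 and 0 of 13, immediate early and heat stress genes 1 and 5 of 17, and fibroblast markers 0 and 1 of 7. The melanocyte regulators MITF and SOX10 had log2 fold changes of 0.01 ± 0.060 and -0.03 ± 0.055, the antigen MLANA 0.05 ± 0.054 and the proliferation marker MKI67 -0.08 ± 0.044, all not called. Of the largest falls, B3GNT7, MAP7D2, FSCN1, PTPRZ1, CDH7 and SIAH3 were not called from the transcript estimated counts (edgeR adjusted p 0.0728 to 0.779). The number of genes lower was 655 without SK-MEL-5 untreated replicate 2 and 665 without treated replicate 3, and the transcript estimated counts gave 390 genes higher and 181 lower.

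In MALME-3M, IFN-γ also raised genes of interferon signalling, antigen presentation and antiviral defence, and some class II genes rose from almost no counts. HLA-DRA had 1 count in the 3 untreated libraries and 52.7 ± 3.6 CPM after treatment, a ratio of 2775 (95% interval 498 to 109650), and CIITA rose from 1.68 ± 0.38 to 137 ± 19 CPM. IRF1 rose from 2.94 ± 0.56 to 253 ± 31 CPM (log2 fold change 6.43 ± 0.12, edgeR adjusted p = 3.4e-18) and WARS from 238 ± 2.5 to 4245 ± 166 CPM. IDO1 had 0 counts before treatment and 4.11 ± 1.1 CPM after it, at least 71.7-fold higher. In all, 1504 genes rose and 1386 fell, 18.3% of those tested, with 376 rises and 112 falls of at least 2-fold. Rises made up 52.0% of these calls, and 46.2% with DESeq2 size factors and 43.9% with upper-quartile scaling. CPM did not overlap between the groups for 33.1% of all tested genes, where chance gives 10%.

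Of the 16 class II genes, 14 rose and 0 fell in MALME-3M (14 and 0 adjusted over the list alone; median 6.55, or 5.84 with 5 members at their bound; camera adjusted p = 2.43e-28). HLA-DPA1 rose from 0.865 ± 0.12 to 92.8 ± 4.2 CPM. HLA-DQB1 rose by 9.45 ± 0.30 on the log2 scale, from 0.075 CPM and thus few counts before treatment. HLA-DRB1, which shares sequence with HLA-DRB5, had 1 count before and 45.1 ± 6.4 CPM after treatment. Class I presentation had 20 of 22 higher and 1 lower (21 and 1 adjusted over the list alone; median 1.77, camera adjusted p = 1.39e-29), with HLA-B from 107 ± 3.0 to 934 ± 26 CPM and TAP1 from 25.2 ± 2.0 to 360 ± 34 CPM. Antiviral genes had 40 of 43 higher and 0 lower (40 and 0 adjusted over the list alone; median 1.59, camera adjusted p = 2.70e-42), with IFITM1, which blocks viral entry, up by 7.95 ± 0.32 and IFI44L by 7.50 ± 0.17. IFN-γ signalling components had 18 of 25 higher and 1 lower (20 and 1 adjusted over the list alone; camera adjusted p = 1.81e-17). GTPases had 8 of 10 higher and 0 lower (8 and 1 adjusted over the list alone; median 3.91, or 3.56 with genes at their bound; camera adjusted p = 2.34e-11), with GBP2 from 7.86 ± 0.47 to 303 ± 22 CPM.

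Further lists were also called higher in MALME-3M, each with only part of its members called. Apolipoproteins L and complement had 9 of 14 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 2.71e-12). SERPING1, the C1 inhibitor, had 0 counts before and 11.6 ± 1.3 CPM after treatment, at least 203-fold higher, and C1S, a protease of the classical pathway, rose by 4.74 ± 0.12. Chemokines and cytokines had 10 of 21 higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 1.52e-06). CXCL10 went from 0 counts to 4.20 ± 1.6 CPM, at least 73.4-fold higher, and CXCL9, another ligand of CXCR3, from 1 count to 6.51 ± 0.97 CPM, a ratio of 339 (95% interval 60.5 to 13431). Checkpoint ligands had 11 of 16 higher and 0 lower (12 and 0 adjusted over the list alone; camera adjusted p = 1.10e-10), with CD274 from 6.76 ± 0.88 to 40.5 ± 7.2 CPM. Cell death genes had 13 of 28 higher and 0 lower (13 and 2 adjusted over the list alone; camera adjusted p = 8.38e-06), and NF-κB targets 7 of 19 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 3.79e-04). With an estimated correlation these 10 lists stayed called, with adjusted p of 1.85e-04 to 0.0365.

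Genes of cell division fell in MALME-3M. Of 28 G2 and M phase genes, 21 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.26, camera adjusted p = 3.13e-13, and adjusted p = 0.0106 with an estimated correlation). MKI67 fell from 1522 ± 83 to 1215 ± 27 CPM (edgeR adjusted p = 2.6e-05) and CCNB2, a mitotic cyclin, from 130 ± 3.4 to 96.2 ± 8.3 CPM, while S phase genes had 3 of 25 lower and 1 higher and were not called. Cholesterol synthesis had 10 of 20 lower and 0 higher (12 and 0 adjusted over the list alone; median -0.25, camera adjusted p = 4.15e-05, and adjusted p = 0.0188 with an estimated correlation). Its members HMGCS1 and SQLE, enzymes of sterol synthesis, were at -0.47 ± 0.083 and -0.45 ± 0.073 and were not called from the transcript estimated counts (edgeR adjusted p = 0.86 and 0.725). Oxidative phosphorylation had 14 of 31 lower and 0 higher (17 and 0 adjusted over the list alone), with UQCRB, a subunit of complex III, at -0.35 ± 0.065 (camera adjusted p = 3.43e-06, and adjusted p = 0.0978 with an estimated correlation). Melanocyte differentiation genes moved both ways, with 12 of 26 lower and 5 higher (15 and 7 adjusted over the list alone; camera adjusted p = 0.0217, and adjusted p = 0.164 with an estimated correlation). DCT, an enzyme of melanin synthesis, fell from 974 ± 13 to 705 ± 81 CPM, the endothelin receptor EDNRB changed by -0.49 ± 0.058, and the channel TRPM1 rose by 0.61 ± 0.080.

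A further 3 lists were called lower in MALME-3M with the preset correlation alone. Replication-dependent histones had 6 of 20 lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.00391, and adjusted p = 0.255 with an estimated correlation), and histone genes share near-identical copies. MYC targets had 5 of 23 lower and 0 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.0144, and adjusted p = 0.164 with an estimated correlation). They included NPM1, a nucleolar chaperone, at -0.28 ± 0.042. Without MALME-3M untreated replicate 1 or treated replicate 2 the MYC list had a camera adjusted p of 0.0580 or 0.0635. The p53 targets had 4 of 21 lower and 2 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0360, and adjusted p = 0.0801 with an estimated correlation), and without untreated replicate 1 or 2 or treated replicate 2 the camera adjusted p was 0.0745, 0.0577 or 0.0528. The lists not called had, higher and lower, 4 and 1 of 14 tryptophan and kynurenine genes, 2 and 4 of 15 iron and ferroptosis genes, 8 and 1 of 30 dedifferentiation and invasion genes, 4 and 0 of 11 neural crest genes and 6 and 3 of 20 MAPK output genes. They also had 0 and 3 of 17 shared melanoma antigens, 5 and 5 of 21 glycolysis genes, 4 and 4 of 18 unfolded protein response genes and 5 and 1 of 17 immediate early and heat stress genes. Constitutive proteasome genes had 6 and 1 of 31, fibroblast markers 1 and 1 of 7, and mitochondrially encoded genes 0 and 0 of 13 (camera adjusted p = 0.461, and called without MALME-3M treated replicate 1).

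Among single genes lower in MALME-3M, CCR1, a chemokine receptor, changed by -1.38 ± 0.15 and KCNAB1, a potassium channel subunit, by -1.41 ± 0.22. SLC7A11, the cystine transporter (chromosome 4, 138164097 to 138242349), fell from 37.5 ± 4.3 to 12.01 ± 0.75 CPM and was not called from the transcript estimated counts (log2 fold change -3.65, edgeR adjusted p = 0.0566). SHROOM3 and RUBCNL had the largest fitted falls, at -4.45 ± 0.91 and -3.88 ± 0.83, and each rested on 1 or 2 untreated libraries. SHROOM3 stood at 142.1, 5.49 and 5.31 CPM and RUBCNL at 20.4, 4.40 and 120.3 CPM in untreated replicates 1, 2 and 3. Neither was called by limma-voom (adjusted p = 0.182 and 0.171) or a robust edgeR fit (0.0545 and 0.0637). From the transcript estimated counts RUBCNL changed sign (log2 fold change 0.76, edgeR adjusted p = 0.644). MITF was at 0.08 ± 0.060 and not called. Of markers of other cell types in lists too small for a set test, KDR was called lower in both lines at -0.42 ± 0.10 in SK-MEL-5 and -0.65 ± 0.094 in MALME-3M, while CDH1 was called lower in SK-MEL-5 at -3.03 ± 0.70. Untreated CDH1 stood at 1.27, 1.34 and 9.53 CPM there, and limma-voom and a robust edgeR fit did not call it (adjusted p = 0.0665 and 0.103). CD68, a lysosomal protein of macrophages, fell from 213 ± 2.6 to 116 ± 5.4 CPM in MALME-3M, where ITGAM was called higher at 1.34 ± 0.43, and PTPRC, VWF, KRT8, KRT18, KRT10 and CD79B were not called in either line. KDR in SK-MEL-5 was not called without untreated replicate 2 (edgeR adjusted p = 0.0589) or from the transcript estimated counts (0.103). The transcript estimated counts gave 518 genes higher and 408 lower in MALME-3M.

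**Figure D1:**
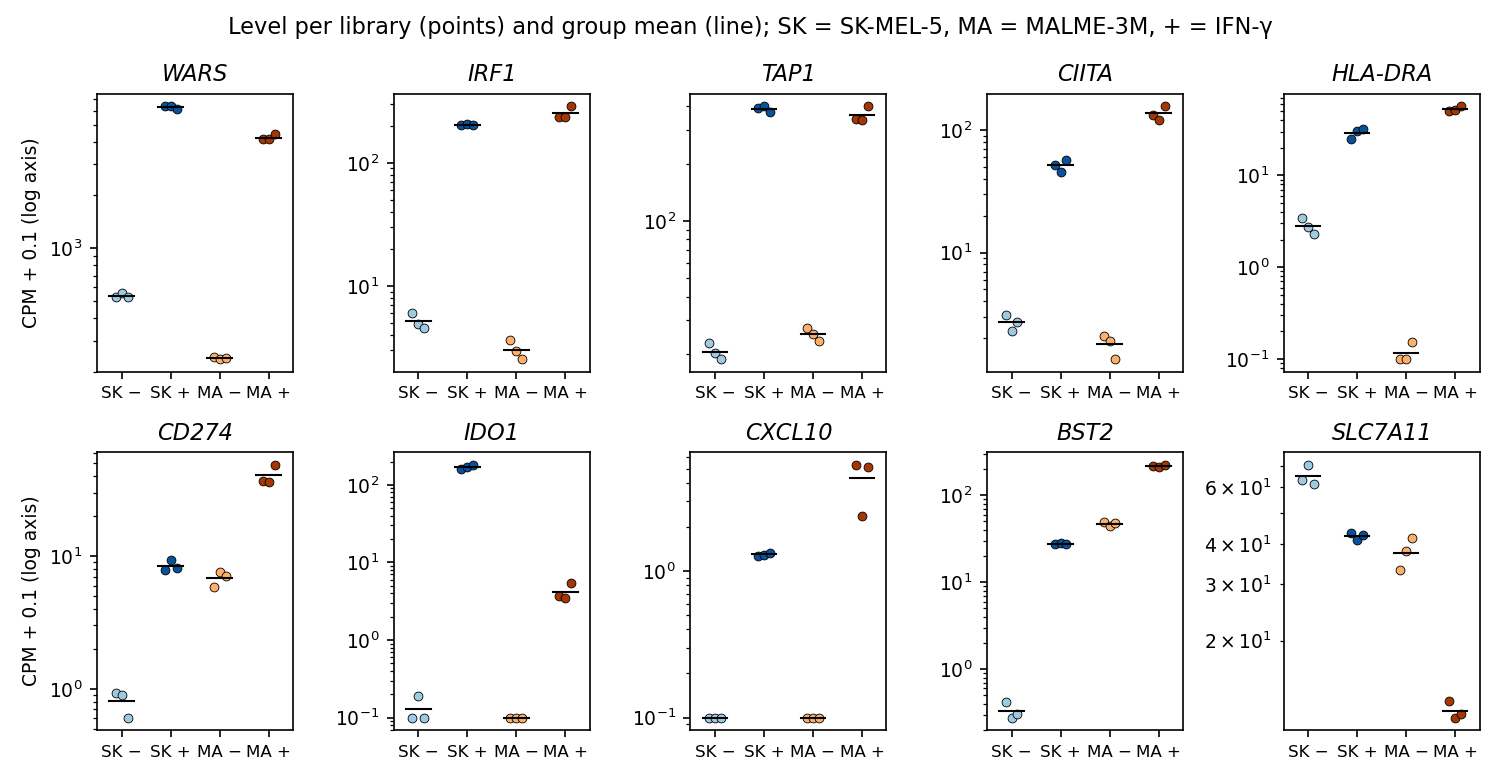
CPM of 10 genes in each of the 12 libraries (points; log axis of CPM + 0.1), by line without (−) and with (+) IFN-γ, with a line at each group mean. HLA-DRA stands at 28.9 CPM in treated SK-MEL-5 and 52.7 CPM in treated MALME-3M, IDO1 at 172 and 4.11 CPM, and SLC7A11 goes from 65.0 to 42.2 CPM and from 37.5 to 12.01 CPM.

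**Figure D2:**
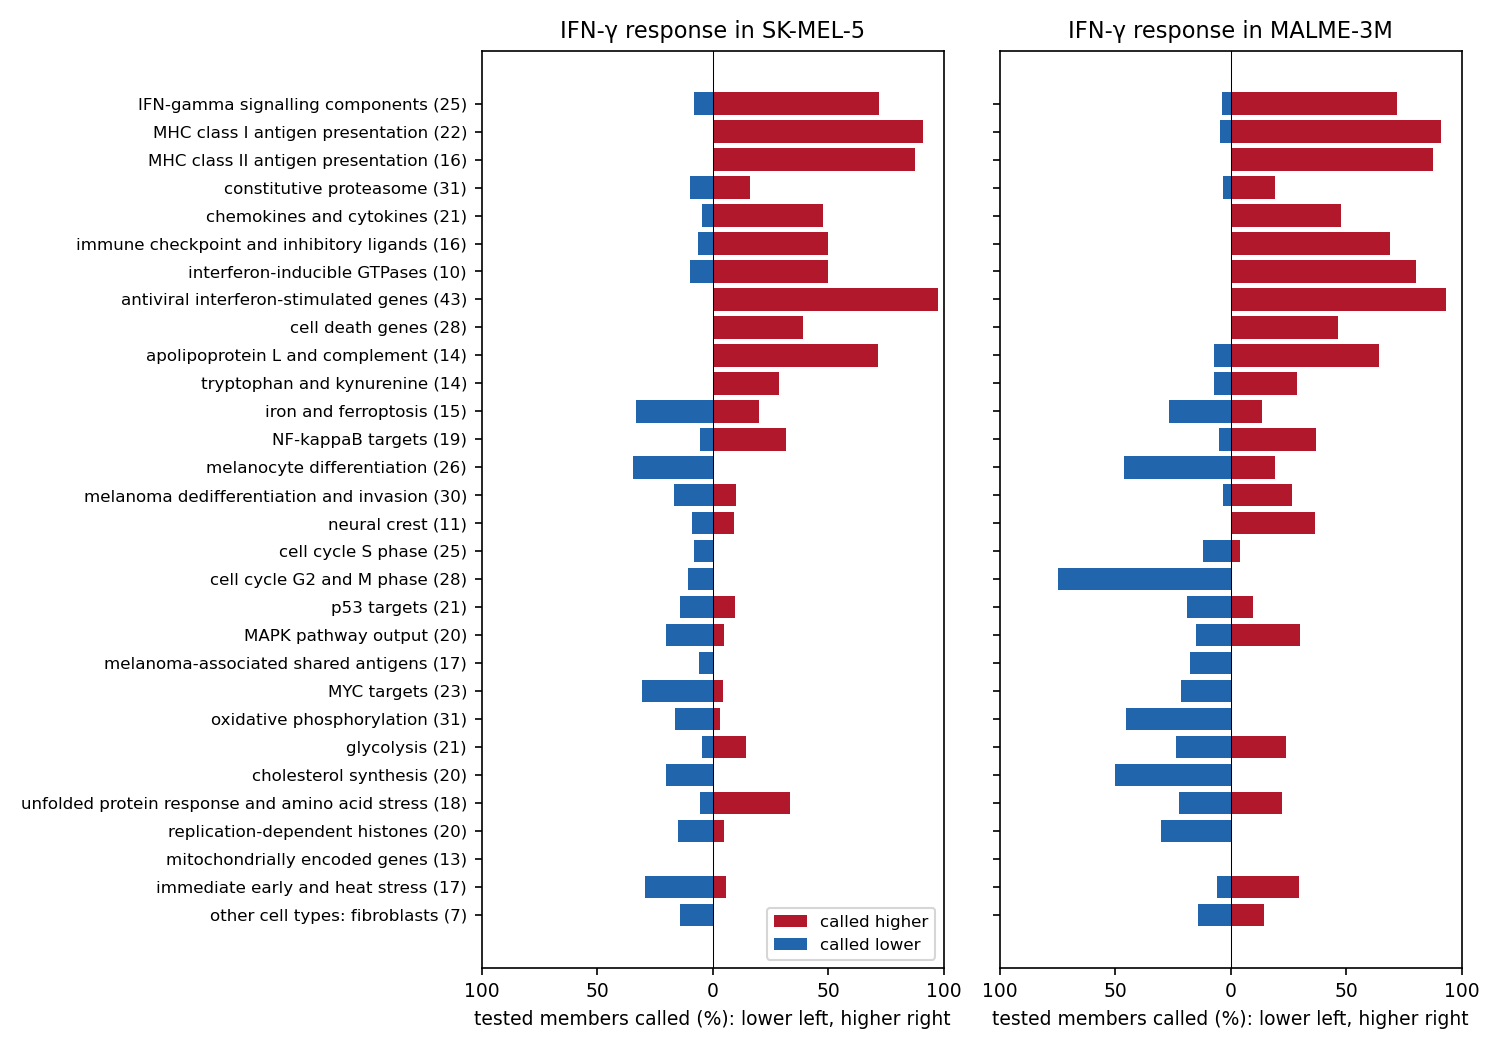
Percent of the tested members of each of 30 gene lists called higher (bars to the right) or lower (bars to the left) after IFN-γ in each line. Antiviral genes reach 42 of 43 higher in SK-MEL-5 and 40 of 43 in MALME-3M, and G2 and M phase genes 3 and 21 of 28 lower.

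The overlap of the responses addressed which changes the lines shared. The rises of IRF1, TAP1, CIITA and WARS were shared, and 576 genes were called higher in both lines, where independent lists of these sizes would share 90.0. They made up 60.9% of the rises in SK-MEL-5 and 38.3% of those in MALME-3M. Another 480 genes were called lower in both, against 97.7 from independent lists, and made up 43.1% of the falls in SK-MEL-5 and 34.6% of those in MALME-3M. Directions called in both lines were opposite for 56 genes. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.44 and a Spearman rho of 0.32 over 15810 genes, and 79.6% of the 3838 genes called in either line changed with the same sign. The number lower in both was 306 without SK-MEL-5 untreated replicate 2, 309 without SK-MEL-5 treated replicate 3 and 68 from the transcript estimated counts, and the number higher in both from those counts was 246.

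**Figure D3:**
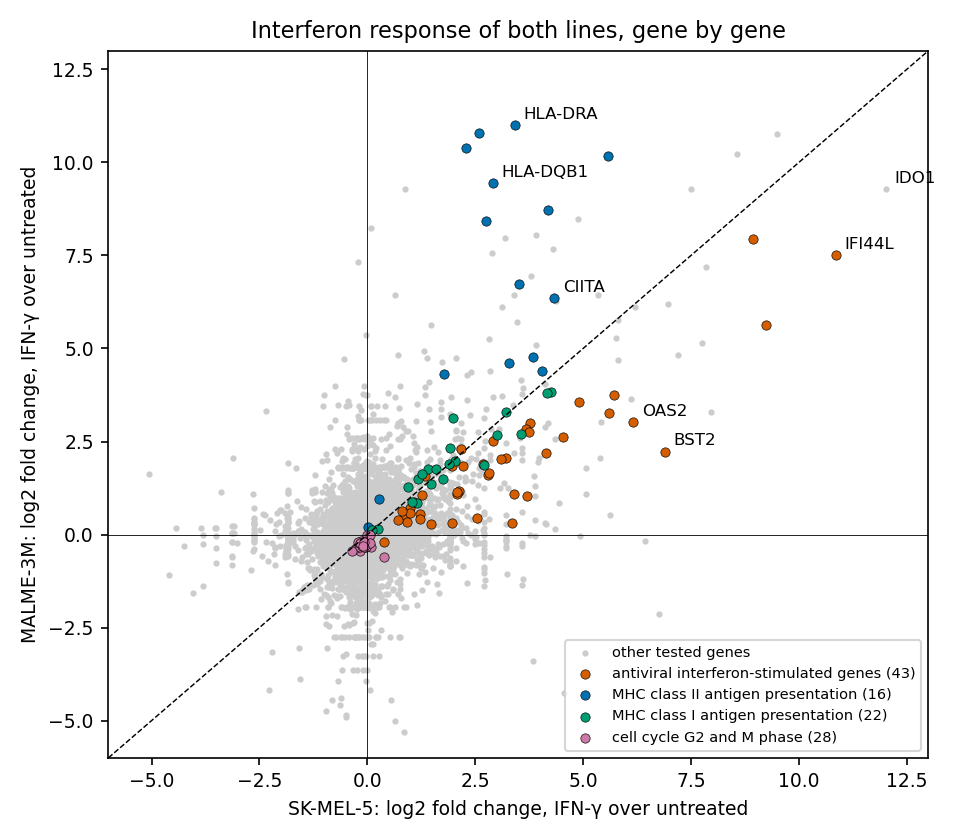
Log2 fold change after IFN-γ in SK-MEL-5 (x axis) and in MALME-3M (y axis) for 15810 genes, with members of 4 lists coloured and a dashed line where both changes are equal; fitted values of genes with a group at 0 depend on the prior count. Of the 43 antiviral genes 27 are called with a smaller change in MALME-3M, and of the 16 class II genes 11 with a larger one.

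The test of the difference in response, MALME-3M minus SK-MEL-5, set class II and antiviral genes apart. Rising more or less here means a larger or smaller log2 fold change, not a larger or smaller gain in CPM. Of 16 class II genes, 11 rose more in MALME-3M and 0 less (13 and 0 adjusted over the list alone; median 2.88, or 2.28 with genes at their bound; camera adjusted p = 8.74e-20, and adjusted p = 5.97e-04 with an estimated correlation). CIITA differed by 2.03 ± 0.23 (edgeR adjusted p = 2.0e-05). HLA-DRA differed by a fitted 7.58, which rests on 1 count in untreated MALME-3M, and its SE of 0.47 understates the error. Of 43 antiviral genes, 27 rose less in MALME-3M and 0 more (33 and 0 adjusted over the list alone; median -0.99, or -0.86 with genes at their bound; camera adjusted p = 5.24e-35, and adjusted p = 5.97e-04 with an estimated correlation). BST2 (chromosome 19, 17402939 to 17405648) differed by -4.66 ± 0.16 and went from 0.233 ± 0.075 to 27.5 ± 0.45 CPM in SK-MEL-5 and from 46.5 ± 2.5 to 218 ± 6.1 CPM in MALME-3M. OAS2 differed by -3.14 ± 0.21 and went from 0.616 to 45.0 CPM and from 9.21 to 75.1 CPM. Untreated SK-MEL-5 had few counts of BST2 and OAS2, so their SE understate the error.

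For the difference, 422 genes were called with a higher and 283 with a lower change in MALME-3M, 4.46% of those tested, and 15 of these 705 genes were called in neither line alone. Of the 576 genes called higher in both lines, 65 rose more in MALME-3M, 81 rose more in SK-MEL-5 and 430 had no called difference. GBP1 differed by -0.05 ± 0.22 and was not called. Among genes that rose more in MALME-3M, BATF3, a transcription factor of dendritic cells, differed by 3.34 ± 0.30, AIM2, a sensor of cytosolic DNA, by 2.99 ± 0.26, C1S by 2.68 ± 0.16 and GBP2 by 2.44 ± 0.13. APOL1 rose less in MALME-3M, at -2.39 ± 0.11, as did OAS1, at -2.66 ± 0.28. CCND1, the G1 cyclin, rose from 240 ± 11 to 418 ± 16 CPM in SK-MEL-5 and differed by -0.70 ± 0.060. The number with a higher change was 240 without MALME-3M treated replicate 3, 275 without treated replicate 1 and 67 from the transcript estimated counts, which also gave 67 with a lower change, and the number lower was 426 with DESeq2. Higher changes made up 59.9% of these calls, and 49.2% with upper-quartile scaling.

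Another 7 lists were called for the difference with the preset correlation and not with an estimated one. GTPases had 2 of 10 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.00287, and adjusted p = 0.0597 with an estimated correlation). G2 and M phase genes had 5 of 28 lower and 0 higher (14 and 0 adjusted over the list alone; camera adjusted p = 4.56e-09, and adjusted p = 0.0723 with an estimated correlation). The unfolded protein response list had 4 of 18 lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.170 with an estimated correlation), with PSAT1, an enzyme of serine synthesis, at -0.45 ± 0.073. Dedifferentiation and invasion genes had 3 of 30 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0229, and adjusted p = 0.354 with an estimated correlation). Oxidative phosphorylation had 1 of 31 lower (3 adjusted over the list alone; camera adjusted p = 0.0120), cholesterol synthesis 1 of 20 (1 adjusted over the list alone; 0.0237) and histones 2 of 20 (3 adjusted over the list alone; 0.0236). With an estimated correlation their adjusted p were 0.387, 0.238 and 0.387. Leaving out 1 library ended the call of these last 3 lists and of the dedifferentiation list. Oxidative phosphorylation had a camera adjusted p of 0.106 without SK-MEL-5 untreated replicate 3. Cholesterol synthesis had 0.0667 and 0.103 without SK-MEL-5 untreated replicates 2 and 3, 0.0772 without SK-MEL-5 treated replicate 1 and 0.0798 without MALME-3M untreated replicate 2. Histones had 0.0926 without SK-MEL-5 untreated replicate 3, 0.116 and 0.0951 without SK-MEL-5 treated replicates 2 and 3, and 0.129 and 0.0600 without MALME-3M untreated replicate 1 and treated replicate 2. Dedifferentiation had 0.0597 without SK-MEL-5 treated replicate 1, and 0.0798 and 0.0981 without MALME-3M untreated replicate 2 and treated replicate 3. Class I presentation, with 3 higher and 5 lower of 22, and IFN-γ signalling, with 3 higher and 4 lower of 25, were not called (camera adjusted p = 0.290 and 0.202).

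The remaining lists were not called for the difference. They had, higher and lower, 1 and 0 of 31 constitutive proteasome genes, 2 and 1 of 21 chemokines and cytokines, 4 and 2 of 16 checkpoint ligands, 3 and 4 of 28 cell death genes and 1 and 6 of 14 apolipoprotein L and complement genes. Tryptophan and kynurenine genes had 2 and 0 of 14, iron and ferroptosis genes 1 and 2 of 15, NF-κB targets 0 and 1 of 19, melanocyte differentiation genes 4 and 2 of 26 and neural crest genes 1 and 0 of 11. The p53 targets had 0 and 1 of 21, MAPK output 2 and 1 of 20, MYC targets 1 and 0 of 23, glycolysis 1 and 1 of 21 and immediate early and heat stress genes 3 and 0 of 17. S phase genes, shared melanoma antigens, mitochondrially encoded genes and fibroblast markers had 0 called members. The mitochondrial list had a camera adjusted p of 0.262, and was called without SK-MEL-5 untreated replicate 1 or MALME-3M treated replicate 1.

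Levels of the treated lines were compared with each other after the data had been seen, to set the differences in fold beside the levels reached. IDO1 was 41.3-fold lower in treated MALME-3M than in treated SK-MEL-5 (log2 difference -5.37 ± 0.13). CD274 was higher in treated MALME-3M by 2.28 ± 0.14, BST2 by 2.99 ± 0.058, CIITA by 1.41 and HLA-DRA by 0.87. Of the 43 antiviral genes, 14 were called higher and 21 lower in treated MALME-3M (median -0.31), and of the 16 class II genes 12 higher and 2 lower (median 1.27). Most genes differed in this comparison, with 5597 of 15810 called higher and 5749 lower, and no list test was run on it. TAP1 and OAS1 reached levels whose difference was not called, at -0.11 (edgeR adjusted p = 0.171) and 0.02 (0.912). Line, dose and culture medium differed together, so none of these differences can be assigned to one of them.

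Untreated MALME-3M and untreated SK-MEL-5 differed in most genes. THBS2, a matrix glycoprotein (chromosome 6, 169215780 to 169254044), stood at 0.248 ± 0.13 CPM in SK-MEL-5 and 1072 ± 13 CPM in MALME-3M, ALDH1A3, an aldehyde dehydrogenase, at 0.157 ± 0.048 and 335 ± 10 CPM, and the adhesion protein CDH1 at 4.05 ± 4.7 and 381 ± 0.49 CPM. In the other direction, GRAMD1B, a sterol transfer protein (chromosome 11, 123358428 to 123627774), stood at 686 ± 1.1 and 0.241 ± 0.22 CPM and TYRP1, an enzyme of melanin synthesis, at 517 ± 4.4 and 6.88 ± 0.60 CPM. In all, 5459 genes were higher in MALME-3M and 5877 lower, 71.7% of those tested, with 2639 and 2608 at least 2-fold. MITF, SOX10 and MLANA differed by -0.03 ± 0.060, 0.03 ± 0.055 and -0.07 ± 0.054 and were not called, and MITF was called higher from the transcript estimated counts (log2 difference 0.53, edgeR adjusted p = 2.9e-05).

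Antiviral genes were already higher in MALME-3M before treatment, with 29 of 43 higher and 7 lower (29 and 7 adjusted over the list alone; median 0.87, or 0.82 with genes at their bound; camera adjusted p = 0.00387, and adjusted p = 0.316 with an estimated correlation). BST2 differed by 7.65 ± 0.12, IFI27 by 6.46 ± 0.21 and OAS2 by 3.87 ± 0.17. These genes had few counts in untreated SK-MEL-5, so their SE understate the error. Class I presentation had 14 of 22 higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.0284, and adjusted p = 0.381 with an estimated correlation). Class II genes had 2 of 16 higher and 11 lower and were not called as a list (median -1.66, camera adjusted p = 0.0564), and were called as one without SK-MEL-5 untreated replicate 1 or 3, MALME-3M untreated replicate 1 or 2, or MALME-3M treated replicate 1 or 3. MYC targets had 20 of 23 lower and 1 higher (20 and 1 adjusted over the list alone; camera adjusted p = 3.82e-04, and adjusted p = 0.316 with an estimated correlation), among them BOP1, a ribosome biogenesis factor, at -1.96 ± 0.065. Shared melanoma antigens had 12 of 17 lower and 4 higher (12 and 4 adjusted over the list alone; camera adjusted p = 0.0369, and adjusted p = 0.316 with an estimated correlation), and glycolysis 14 of 21 higher and 5 lower (14 and 5 adjusted over the list alone; camera adjusted p = 0.0284, and adjusted p = 0.381 with an estimated correlation). MAGEC2, an antigen of testis and tumours, differed by -3.63 ± 0.092 and ENO2, an enolase, by 4.04 ± 0.078.

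The other lists were not called between the untreated lines. They had, higher and lower in MALME-3M, 4 and 11 of 21 chemokines and cytokines, 7 and 2 of 10 GTPases, 8 and 5 of 16 checkpoint ligands, 13 and 7 of 25 IFN-γ signalling components and 13 and 9 of 26 melanocyte differentiation genes. CXCL8, a neutrophil chemokine, differed by -4.58 ± 0.35, IL6 by -4.10 ± 0.18 and CD274 by 3.24 ± 0.21. Constitutive proteasome genes had 4 and 17 of 31, cell death genes 10 and 8 of 28, apolipoproteins L and complement 7 and 2 of 14, tryptophan genes 4 and 8 of 14 and iron and ferroptosis genes 3 and 10 of 15. NF-κB targets had 8 and 10 of 19, dedifferentiation and invasion genes 9 and 16 of 30, neural crest genes 2 and 5 of 11, S phase genes 5 and 15 of 25 and G2 and M phase genes 11 and 9 of 28. The p53 targets had 7 and 6 of 21, MAPK output 11 and 7 of 20, oxidative phosphorylation 7 and 15 of 31, cholesterol synthesis 6 and 12 of 20 and the unfolded protein response list 3 and 7 of 18. Histones had 8 and 9 of 20, mitochondrially encoded genes 5 and 4 of 13, heat stress genes 3 and 10 of 17 and fibroblast markers 1 and 5 of 7. LUM, a proteoglycan of fibroblasts, stood at 161 ± 15 CPM in SK-MEL-5 and 13.1 ± 1.7 CPM in MALME-3M. The transcript estimated counts gave 3531 genes higher and 3591 lower.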

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

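The results given here differed between the lines in a test of the difference in response itself (MALME-3M minus SK-MEL-5, edgeR quasi-likelihood test). All tests of explanations in this part except the counts of other splits were chosen after the results they bear on had been seen.

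The change was called higher in MALME-3M for 422 genes and lower for 283. Of 100 labellings drawn from the 200 possible ones that split treated and untreated libraries within each line, 2 gave 705 or more calls, the real one included. The other was the real labelling with the treatment of one line swapped, which gave 3576 calls, and the highest of the rest gave 535. The rest mix treated with untreated libraries in at least 1 line, which puts the response into the spread within groups. They therefore cannot tell different responses of the lines from equal ones. Of the same 100 labellings 47 gave 9 or more called lists, with up to 17, so chance is not excluded for the number of lists.

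The first pattern weighed is the smaller fold rise of antiviral genes in MALME-3M, with a list median difference of -0.99. After treatment 14 of 43 members were called higher there and 21 lower (median -0.31), where 5597 of all 15810 genes were higher and 5749 lower. A weaker response of every interferon target is argued against by the 65 of 576 genes called higher in both lines (11.28%) that rose more in MALME-3M. The higher untreated level in MALME-3M is argued against for the 14 members not called higher before treatment, whose median difference was -0.4697, with 13 of them negative and 5 called. For the 29 members called higher before treatment it stays open: the slope of the treated on the untreated difference between the lines was 0.561 ± 0.077, between the 0 of equal treated levels and the 0.954 of genes called in neither line, and a ceiling on these genes may account for part of their smaller rise. Line, dose and medium stay open and untested.

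The second pattern is the larger rise of class II genes in MALME-3M, with a list median difference of 2.88. Of 5 members with little coding variation, 4 were called with a larger rise, among them HLA-DRA, which had almost no counts in untreated MALME-3M. This says little about alleles that differ from the reference. A line carries the same alleles before and after treatment, so their effect largely cancels in a fold. Levels compared between the lines may still carry it, which was not tested. Few counts in untreated MALME-3M are argued against as the whole explanation by the 9 members with at least 10 counts in each group. Their median difference was 0.9359, with 5 of these 9 called. It lies below the list median of 2.88, so few counts may account for part of that median. After treatment 12 of the 16 class II genes were called higher in MALME-3M and 2 lower (median 1.27), while before it 2 were higher and 11 lower (median -1.66). Most of all tested genes were called in both of these comparisons, and no list test was run between the treated lines. Line, dose and medium, which the design cannot part, may lie behind both.

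The third pattern is a gene count far higher in 1 of 3 libraries of a group, which bears on single large changes such as that of SHROOM3 in MALME-3M. There were 30 such jumps in 21 genes, each at least 8 times the median of its group plus 1 CPM. Of the genes with a jump in the groups compared, 3 were called in SK-MEL-5, 7 in MALME-3M and 7 between the untreated lines. Of all tested genes, 13.03%, 18.3% and 71.7% were called in these comparisons. Of the jumps 46.67% lay in treated libraries (14 of 30, 95% Clopper-Pearson interval 28.3% to 65.7%). The interval takes jumps as independent, though genes such as STAB2 recur in several groups. The libraries of a group share their treatment, so exposure to interferon could hardly raise 1 of them alone, and this share tests little. Of the 20 jumps with summed annotated transcripts 10 had sums of 0 in the library and the group median and decide nothing, and 100% of the other 10 rose under 2-fold there, so a candidate explanation for these is reads counted at the gene that did not come from its annotated transcripts.

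The difference (MALME-3M minus SK-MEL-5) was called positive for HLA-DRA (7.58), CXCL9 (4.80), BATF3 (3.34), HLA-DPA1 (3.23), VWA1 (3.11), AIM2 (2.99), CDH1 (2.80), C1S (2.68), LRP2 (2.64), CIITA (2.03), IRF1 (1.08) and B2M (0.41). It came from larger fold rises in MALME-3M, except for CDH1, called lower in SK-MEL-5 alone. LRP2 gained more CPM in SK-MEL-5, from 65.6 to 165, than in MALME-3M, from 0.253 to 3.96. So did BATF3, from 9.63 to 25.4 CPM in SK-MEL-5 and from 0.437 to 11.8 CPM in MALME-3M. AIM2 started lower in MALME-3M, at 0.428 against 2.96 CPM. Its treated levels, 29.4 CPM there and 26.0 CPM in SK-MEL-5, had no called difference (edgeR adjusted p = 0.155). CXCL9 was not called without any one of 6 libraries, SK-MEL-5 untreated replicates 1 and 2 and treated replicate 3 and MALME-3M untreated replicates 1 and 3 and treated replicate 3 (adjusted p 0.0527 to 0.294). CDH1 was not called without any one of 9 libraries, the treated ones of SK-MEL-5 and all of MALME-3M (adjusted p 0.0655 to 0.135). CDH1 was also not called with the filter of 1 CPM, DESeq2, limma-voom or a robust fit, nor IRF1 with limma-voom, and neither CDH1 nor CXCL9 was called from the transcript estimated counts. VWA1, HLA-DPA1, LRP2 and IRF1 were not called from the transcript estimated counts (adjusted p 0.83, 0.113, 0.518 and 0.29).

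The difference was called negative for MKI67 (-0.24), TAP1 (-0.41), CD274 (-0.97), DDX58 (-2.09), IFI44 (-2.31), IFI27 (-2.34), APOL1 (-2.39), KCNIP4 (-2.39), OAS1 (-2.66), OAS2 (-3.14) and BST2 (-4.66). It came from smaller fold rises in MALME-3M, except for MKI67, which fell more there, and KCNIP4, called higher in SK-MEL-5 alone. In CPM, BST2, APOL1, IFI27, IFI44, OAS2 and CD274 gained more in MALME-3M, and TAP1, DDX58 and OAS1 gained less. APOL1 went from 21.6 to 177 CPM in MALME-3M and from 2.15 to 94.1 CPM in SK-MEL-5. MKI67 was not called without SK-MEL-5 untreated replicate 1, SK-MEL-5 treated replicate 1 or 3, MALME-3M untreated replicate 1 or MALME-3M treated replicate 2 (adjusted p 0.0511 to 0.085). TAP1 was not called without any one of 8 libraries, all but SK-MEL-5 untreated replicate 1, MALME-3M untreated replicate 3 and MALME-3M treated replicates 1 and 3 (adjusted p 0.0522 to 0.102). CD274 was not called without any one of 10 libraries, all but MALME-3M untreated replicate 1 and treated replicate 3 (adjusted p 0.0530 to 0.176). TAP1 and CD274 were not called by limma-voom (adjusted p 0.0948 and 0.315) or from the transcript estimated counts, where TAP1 changed sign. DDX58 and IFI27 were not called from the transcript estimated counts (adjusted p 0.959 and 0.193).

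Among gene lists, the median difference was 0.13 for GTPases, 0.17 for dedifferentiation and invasion genes, -0.19 for G2 and M phase genes, -0.085 for oxidative phosphorylation, -0.10 for cholesterol synthesis, -0.13 for the unfolded protein response and -0.074 for histones, beside the class II and antiviral lists above. Of these 9 lists, called by camera with a preset correlation, class II and antiviral genes stayed called with an estimated one.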

How the results depend on the processing

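Fitting one line alone could not be run for the difference between lines. No paired analysis was possible because the labels give the libraries no replicate numbers. Of the tests in this part, the robust fit and leaving out assembled loci were chosen after the data had been seen. The transcript estimated counts summed to genes hold 49.9% to 55.2% of all estimated counts, so they measure genes in part only. Among named genes, 67 of 116 calls in SK-MEL-5, 82 of 125 in MALME-3M, 32 of 80 for the difference and 126 of 140 between the untreated lines were kept under every alternative but the fold threshold and the left-out libraries, and 90, 111, 55 and 135 with every library left out in turn. Among gene lists 12 of 16, 12 of 17, 2 of 9 and 0 of 5 were kept under every alternative, and 13, 15, 5 and 5 with every library left out. The transcript estimated counts, with 12502 genes tested, called 390 genes higher and 181 lower in SK-MEL-5, 518 and 408 in MALME-3M, 67 and 67 for the difference, 3531 and 3591 between the untreated lines, and 246 and 68 in both lines. These counts also reversed the sign of NDUFA9 (-0.30), JAK2 (-0.57), PPARGC1A (0.074), UQCRFS1 (0.0070) and ODC1 (0.89) in SK-MEL-5, of RUBCNL (0.76) in MALME-3M, of PFKFB4 (-0.21), SPRY4 (-0.34), IDI1 (0.010) and TAP1 (0.30) for the difference, and of PSMA1 (-1.04, adjusted p = 4.0e-06), TAP1 (-0.45) and MITF (0.53) between the untreated lines; the cause was not tested. A log2 fold change of at least 1 in addition left 314 and 44 in SK-MEL-5, 376 and 112 in MALME-3M, 80 and 73 for the difference, 2639 and 2608 between the untreated lines, and 190 and 4 in both lines, by its construction. The Wald test of DESeq2 gave 426 genes lower for the difference, and the cause was not tested. Camera with an estimated correlation called 2 lists for the difference and 0 between the untreated lines, where fry, which does not compare a list with other genes, called 26. With 1 library left out in turn, SK-MEL-5 had 709 to 1100 genes higher and 655 to 1148 lower, MALME-3M 1099 to 1533 and 1013 to 1405, the difference 240 to 355 and 204 to 362, the untreated lines 5229 to 5914 and 5642 to 5949, and both lines 484 to 562 and 306 to 442. The lowest values came without SK-MEL-5 untreated replicate 2 (655 and 306) and MALME-3M treated replicate 3 (240), and lists called ranged over 13 to 17, 15 to 18, 6 to 10 and 5 to 6. The 3 against 3 libraries of one comparison make 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 2060, 2890 and 11336 genes in SK-MEL-5, MALME-3M and the untreated lines, and every other split 0. It gave 16, 17 and 5 lists, against at most 10, 12 and 3 in the others. Every other split mixes libraries of both kinds in each group, which puts the effect into the spread within groups. Its 0 called genes therefore say little. Genes called in both lines numbered 1056 in the real labelling and at most 56 in the other 99 labellings within lines, so 1 of 100 was as large. Nearly all of these labellings mix treated with untreated libraries and so bear on a response to treatment. They cannot tell whether 2 real responses share genes by chance. Depth limits genes near the floor of 3 counts over a group, such as CXCL10 and IDO1 before treatment and HLA-DRA in untreated MALME-3M, whose folds are bounds or wide intervals, and more counts would narrow these.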

Other observations

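The patterns of this part and the genes named were picked after the values had been seen, and the tests of a loss on chromosome 9 and of the zinc finger genes' share were chosen after the results they bear on. SK-MEL-5 lacked transcripts of neighbouring genes on the short arm of chromosome 9 that MALME-3M expressed. CAAP1, PLAA, IFT74, MOB3B and C9orf72, from 26840685 to 27573866 (GENCODE 29 on GRCh38), all stood below 0.2 CPM in SK-MEL-5 and at 5 CPM or more in MALME-3M. In a wider gap of 11049223 bp between KLHL9 and ACO1 (21335380 to 32384603), the 9 genes with at least 10 counts in a line had 19981 counts in MALME-3M and 21 in SK-MEL-5. Of the 21, 17 lay in CDKN2B-AS1, an antisense gene with 38 counts in MALME-3M, which was low in both lines (0.166 and 0.347 CPM). ELAVL2, a neuronal RNA-binding protein, had 0 and 1788 counts in the 6 libraries of SK-MEL-5 and of MALME-3M, and TUSC1 0 and 537. The cell cycle inhibitors CDKN2A and CDKN2B had 0 counts in both lines, and MTAP, an enzyme of methionine salvage, had 4 in SK-MEL-5 and 6 in MALME-3M. KLHL9, an adaptor of a ubiquitin ligase, went the other way, with 3160 counts in SK-MEL-5 and 0 in MALME-3M.

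MALME-3M in turn lacked transcripts of zinc finger genes of chromosome 19, a family of transcriptional repressors that lies in clusters. Of 110 such genes at 5 CPM or more in SK-MEL-5, 14 stood below 0.2 CPM in MALME-3M (12.7%), against 144 of 9382 other protein-coding genes (1.53%). In SK-MEL-5 0 of 85 were below 0.2 CPM. ZNF331 had 22.7 CPM in untreated SK-MEL-5 and 0.069 CPM in untreated MALME-3M, and ZFP30 had 10.5 and 0 CPM.

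A hypothesis for the genes of chromosome 9 is that SK-MEL-5 may have lost both copies of the segment. The 5 genes were picked for being near 0 and cannot test this, and the only other gene of the interval with at least 10 counts, TEK, had 17 counts in MALME-3M and 0 in SK-MEL-5, too few to decide. Loss and silencing cannot be told apart here, and DNA would be needed. Chance neighbours among genes near 0 are argued against by a permutation p of 1e-04, the smallest that 10000 permutations can give, with a longest run of 4 among them. These permutations placed genes freely and did not keep neighbours together, so they do not cover neighbours that are regulated alike. In MALME-3M the longest run was 3 genes, on chromosome 5, with a permutation p of 0.02. The lack of transcripts of both CDKN2A and MTAP in both lines was not tested further.

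For the zinc finger genes, the family was picked after its members were seen, so 21 families of at least 10 genes of 1 chromosome were scanned, with the labels of genes near 0 rotated along the genome so that neighbours stayed together. A chance share is argued against by 3 of 9492 rotations, the real one included, with a family as extreme (permutation p = 0.000316). Loss of a single segment is argued against by 207 genes at 5 CPM or more in MALME-3M that lie between the first and the last of the 14. Silencing of clusters, or several small losses, may be at work, and neither was tested.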
